A study of Danio rerio with 5 samples.

How the data were processed

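RNA of whole zebrafish larvae at 7 days after fertilization was measured on Affymetrix zebrafish arrays, per the labels' protocols. Each array received biotin-labelled cRNA made from 6 µg of total RNA of a pool of 20 animals. The labels assign 1 array to the unirradiated control, 1 to 12 Gy and 3 to 15 Gy of protons given at 24 h. No batch, scan date or clutch was given in the sources used here, so batches could not be tested.

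The deposited values are 1 intensity per probe set and array, on a linear scale from 3.99 to 24171. The submitters' processing notes name RMA, which corrects the background, normalizes arrays to common quantiles and summarizes the probes of a set. RMA gives log2 values, so the deposited intensities appear to be RMA values returned to a linear scale. That reading comes from the values and is stated by no label. The RMA version, its software and the chip definition are not given in the sources used here. The quartiles of the arrays were close but not equal (medians 61.9 to 65.2), so another normalization was among the alternatives. Scanner files were not used here, so background correction and detection calls could not be redone, and no probe set was called present or absent. RMA can shrink large differences of dim probe sets, and quantile normalization assumes that most transcripts do not differ.

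Values were turned to log2 without an added constant, since no value was below 1. The 115 control probe sets were left out, and the remaining 15502 were tested. Gene names came from the platform's annotation table and were updated through Entrez identifiers with the RefSeq table of assembly GRCz12tu, used only for names. Of the probe sets, 10795 had 1 symbol, 135 had several and were not named, and 4572 were not listed in the table. Of the 10795, 10711 matched by identifier and 1 symbol changed. A gene with several probe sets was represented by the probe set with the highest mean over all arrays, which left 8793 genes. Values identical to 8 decimals in 2 or more arrays occurred in 3879 probe sets, and in all 3 arrays at 15 Gy in 174. Ties among the 15 Gy arrays lower the estimated spread. For mdm2 the tie was between the 12 Gy array and 15 Gy replicate 2.

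The analysis used limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. A single limma model with a mean per group was fitted to all 5 arrays. Its 2 residual degrees of freedom all came from the 15 Gy arrays, and the prior added 1.20. The control and 12 Gy arrays were thus assumed to vary as the 15 Gy arrays did. The comparisons were 15 Gy against control, 12 Gy against control and 15 Gy against 12 Gy, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Differences are on the log2 scale, and an SE is the moderated standard error of the fit.

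Gene lists numbered 36 and were fixed with their members before the data were examined. They were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. With a correlation estimated from the data, 0 lists passed in any comparison, and that adjusted p is printed beside each call. On simulated data of this design, that test also passed 0 of 4 lists moved by 1 on the log2 scale. Not passing it therefore leaves undecided whether a list moved. With fry, which asks whether a list's genes move on balance one way, 0 lists passed either (smallest adjusted p = 0.106 for 15 Gy against control, 0.168 for 12 Gy against control and 0.0724 for 15 Gy against 12 Gy). Of 1044 genes in the lists, 42 were in more than 1 list, and 23 members were matched through older names, which put cxxc1b, not a photoreceptor gene, in the photoreceptor list. Adjustment over the members of a list alone was added to the naming rule after no probe set had passed over all, and the counts by size were added for the same reason.

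Named genes followed a rule that, but for the adjustment over a list alone, was fixed before the data were examined. It took the 10 largest increases and 10 largest decreases at 15 Gy against control, and 5 each way in the other comparisons. It required a single symbol that is not a clone name and all 15 Gy arrays on the same side. Genes past the threshold came first, and the largest other changes filled the places as values only. The rule also took up to 4 members of each list that passed and up to 2 of the others, and always mdm2, cdkn1a, ccng1, baxa and gadd45aa. A list, which the counts of lists include, and a further gene of the rule are not reported here. Genes named outside it are said in the text to be chosen after their values were seen, or stand as members that a count of 5 or fewer covers. The clock activators clocka and clockb were named after their values were seen, and ptprc, lcp1, mpx and csf1ra were added in the same way as contrasts.

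The steps were tested on simulated data for 15502 probe sets with 200 changed, which were drawn at random and varied independently. With each probe set's measured residual SD, 18%, 60%, 74% and 94% of changes of 1, 2, 4 and 6 on the log2 scale were recovered for 15 Gy against control, and 8%, 40%, 66% and 90% for 12 Gy against control. In simulated lists over 8793 genes, 4 of 4 moved lists passed with the preset correlation, 0 with an estimated one, and 0 unmoved lists passed. The simulated genes varied independently, so this does not show how often unmoved lists would pass in arrays whose genes vary together. Likeness of the changes at both doses was set beside 100 simulations of unchanged groups that shared the control array.

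Alternatives were another quantile normalization, median centring, cyclic loess, leaving out the dimmest 30% of probe sets, each 15 Gy array left out, a trended or robust prior, a minimum change, limma's treat against 1.2-fold, 1 probe set per gene, and control probe sets kept in. Further ones were all irradiated arrays as 1 group, dose as a linear term, an estimated list correlation, the mean of a gene's probe sets, and list medians against 10000 random lists matched on expression. Fits without tied probe sets and on the brightest probe sets, and fry, were added after seeing the data.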

Results

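Gene expression was measured in whole zebrafish larvae of the AB strain at 7 days after fertilization. The embryos had been irradiated with protons at 24 h after fertilization, or left unirradiated as controls. Protons are charged particles, and the beam had an energy of 8 MeV/u and delivered 7.5 Gy/min, where the gray (Gy) is the unit of absorbed dose. The 5 arrays comprised 1 pool of control larvae, 1 pool after 12 Gy and 3 pools after 15 Gy, each of 20 animals taken from a group of 60. The labels call the pools biological replicates but do not say that the 15 Gy pools came from separate irradiations, so p-values measured the spread between these pools. The 15502 probe sets that were not controls stood for 8793 named genes. The median log2 intensity ran from 5.95 in the control array to 6.03 in 15 Gy replicate 2. The number of arrays limited the precision, since the control and the 12 Gy group had no replicate.

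The arrays differed mainly along an axis with the control at an end. The first principal component held 79.7% of the variance and placed the control array at −66.1, the 12 Gy array at 3.78, and 15 Gy replicates 1, 2 and 3 at 49.2, −4.32 and 17.4. The next component held 12.5% and placed the 12 Gy array, at −29.2, apart from the others. The control array lay at least 2-fold above all other arrays in 403 probe sets and at least 2-fold below them in 538. The corresponding counts for 15 Gy replicate 1 were 10 and 237, and those for the 12 Gy array were 37 and 10. The ratio of the 5′ to the 3′ actin control probe set, a sign of RNA quality, was 0.0171 in the control array, 0.0354 at 12 Gy and 0.129, 0.0350 and 0.108 in 15 Gy replicates 1, 2 and 3. For GAPDH the same ratio was 0.174 in the control array, 0.177 at 12 Gy and 0.242, 0.189 and 0.228 at 15 Gy. A lower ratio means less signal at the 5′ end relative to the 3′ end, and both ratios were lowest in the control array.

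The first comparison asked which transcripts differed between larvae irradiated with 15 Gy and unirradiated larvae. The genes below had the largest differences among named genes, each represented by its probe set with the highest mean, whose 3 arrays at 15 Gy lay on the same side of the control. Those with the largest increases included matrix metallopeptidase genes, and those with the largest decreases included 3 cone opsin genes. The transcript of mmp9, which encodes a secreted metallopeptidase that degrades extracellular matrix, was 71.8-fold higher at 15 Gy (log2 12.05 ± 0.39, SD, n = 3) than in the control array (5.88), and that of mmp13a, a collagenase gene, was 56.3-fold higher. Also higher were the inducible chaperone gene hsp70.3 (38.9-fold), irg1l (37.9-fold), the metallopeptidase inhibitor gene timp2b (26.7-fold), the cytokine signalling inhibitor gene socs3a (24.7-fold), the prostaglandin synthase gene ptgs2a (19.5-fold), anxa2a (16.3-fold), the transcription factor gene cebpb (15.3-fold) and moxd1 (14.6-fold). The value for hsp70.3 is uncertain as to the gene, because the gene has near-identical copies. Among the lowest, the blue cone opsin gene opn1sw2 was 10.6-fold lower (9.68 ± 2.24 against 13.09), the green cone opsin gene opn1mw1 8.87-fold lower and the ultraviolet cone opsin gene opn1sw1 8.28-fold lower. They were joined by nme2a (8.92-fold), the cone phosphodiesterase gene pde6c (8.89-fold), pdcb (7.55-fold), calb2b (7.53-fold), gnb3b (7.46-fold), rgs9a (7.36-fold) and the cone transducin gene gnat2 (7.33-fold).

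None of these genes passed the test over all probe sets. With limma, 0 of 15502 probe sets reached an adjusted p of 0.05 for 15 Gy against control, and the smallest adjusted p was 0.167, which was also that of mmp9 and of the other 9 named genes with the largest increases. At an unadjusted p of 0.05, 4062 probe sets (26.2%) passed, 2195 of them higher and 1867 lower at 15 Gy. When all 4 irradiated arrays were taken as 1 group against the control, 6 probe sets passed. Among them were mmp9, the epithelial cadherin gene cdh1, emd and the photoreceptor gene rgs9b. Of these, rgs9b was lower, and dim in the irradiated arrays. The gene emd was named after its value was seen. The adjusted p of the opsin genes was higher still, 0.341 for opn1sw2, because the 3 arrays at 15 Gy themselves ranged from 7.13 to 11.36 for this gene. In simulated data of this design with each probe set's measured residual SD, the test recovered 60% of the probe sets that differed by 2 on the log2 scale and 94% of those that differed by 6. The simulated changes fell on probe sets drawn at random, so these shares need not hold for the genes named above. Of those, mmp9 differed by 6.17 and did not pass.

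**Figure D1:**
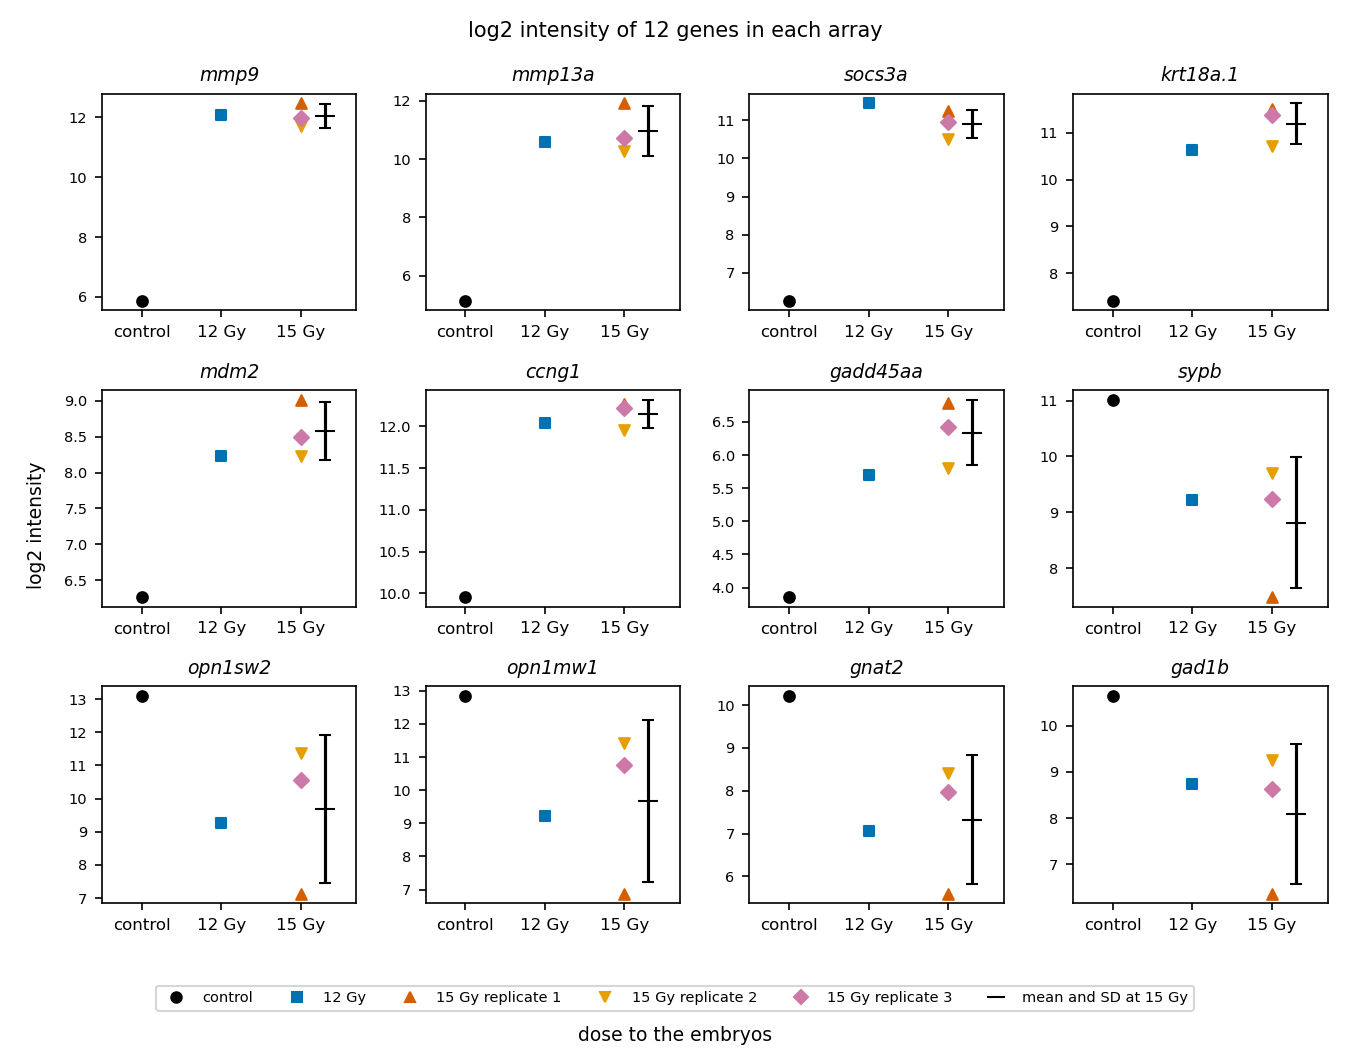
Each panel shows the log2 intensity of a gene (y axis, own range) by dose (x axis), with a point per array and, at 15 Gy, the mean and SD of the 3 arrays. For mmp9 the 4 irradiated arrays lay between 11.70 and 12.47 against 5.88 in the control, whereas for opn1sw2 they lay between 7.13 and 11.36 against 13.09.

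By size, 642 probe sets were at least 2-fold higher and 435 at least 2-fold lower than in the control in each of the 3 arrays at 15 Gy. These counts, chosen after the test had made no calls, covered 466 and 229 named genes. With another array in the place of the control as the lone array, the total of 1077 became 290 for 15 Gy replicate 1, 0 for replicate 2 and 5 for replicate 3. These 4 arrangements are too few for a share under 0.05. Without 15 Gy replicate 2, the total was 1887.

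Of the 36 gene lists, 18 passed at 15 Gy, 13 higher and 5 lower, and 0 with an estimated correlation. Genes of inflammation and the acute phase rose as a group (24 genes, median log2 change 2.26, camera adjusted p = 1.59e-08; adjusted p = 0.782 with an estimated correlation). Of the 24 genes, 19 rose and 0 fell adjusted over the list alone, against 0 when adjusted over all probe sets. The 19 included mmp9, mmp13a, timp2b and socs3a. Without 15 Gy replicate 1, 2 or 3 the count was 17, 14 and 0. The list median lay 2.58, 1.81 and 2.25 above the control in replicates 1, 2 and 3, all taken from the same control array. The 5 arrays ranked in the same order by this median and by the actin 5′ to 3′ ratio, from the control (0.0171) to replicate 1 (0.129). Myeloid cell genes also rose as a group (29 genes, median 0.59, camera adjusted p = 0.000102; adjusted p = 0.782 with an estimated correlation), with 7 members past the threshold adjusted over the list alone. The largest of these 7 were mmp9, mmp13a, cebpb and srgn (3.14), of which the first 3 are also in the inflammation list. The leukocyte genes ptprc (0.59) and lcp1 (1.21) were among the 7, whereas the neutrophil peroxidase gene mpx (0.15) and the macrophage receptor gene csf1ra (0.00) were not. Without replicate 1, 2 or 3 the count of 7 became 5, 10 and 0.

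Genes of the interferon response rose as a group (18 genes, median 0.33, camera adjusted p = 0.0378; adjusted p = 0.782 with an estimated correlation). In this list 5 genes rose adjusted over the list alone, led by isg15 (2.69) and irf1b (2.07), and 6, 0 and 0 passed without replicate 1, 2 or 3. The list's call was also lost without replicate 2 (adjusted p = 0.0768). Genes of proteins that the liver secretes rose as a group (45 genes, median 0.57, camera adjusted p = 0.00158; adjusted p = 0.782 with an estimated correlation). Among these, 8 rose adjusted over the list alone, including the fibrinogen chain genes fgb (2.95), fga (2.79) and fgg (2.60) and the apolipoprotein gene apoeb (2.62). This count was 0, 13 and 0 without replicate 1, 2 or 3.

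Among the genes chosen beforehand to be named whatever their value, mdm2, which encodes a ubiquitin ligase, was 4.98-fold higher at 15 Gy than in the control (SE 0.37 on the log2 scale), and the cyclin gene ccng1 was 4.56-fold higher (SE 0.17). The stress-response gene gadd45aa was 5.58-fold higher (SE 0.46) and the proapoptotic gene baxa 2.04-fold higher (SE 0.19). The adjusted p over all probe sets was 0.167 for each of these 4 genes. The gene cdkn1a was not analysed here, as no probe set carried its symbol alone. The apoptosis list rose as a group (29 genes, median 0.34, camera adjusted p = 0.0299; adjusted p = 0.782 with an estimated correlation), although 0 of its members passed adjusted over the list alone. DNA repair genes (26 genes, median 0.01, camera adjusted p = 0.968) and cell cycle and replication genes (50 genes, median −0.08, camera adjusted p = 0.284) did not pass as groups.

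Photoreceptor genes fell as a group (42 genes, median log2 change −1.85, camera adjusted p = 7.94e-09; adjusted p = 0.782 with an estimated correlation). All 42 lay below the control in each of the 3 arrays at 15 Gy, a position that 36.5% of all named genes shared and that chance gives 25% of genes. Only 1 of the 42 passed adjusted over the list alone, the G-protein regulator gene rgs9b, which fell by 1.56 on the log2 scale (SE 0.07). From 5.41 in the control, rgs9b fell to 3.85 ± 0.03 (SD, n = 3) at 15 Gy, below the lower quartile of every array. Its small SE thus belongs to a dim probe set. Without replicate 1, 2 or 3 the count was 3, 0 and 0. The list median was −2.77, −1.06 and −1.58 in replicates 1, 2 and 3, so replicate 1 lay farther from the control than the others. Genes of neurons and synapses fell as a group (38 genes, median −1.58, camera adjusted p = 3.04e-08; adjusted p = 0.782 with an estimated correlation), with 37 of 38 below the control in every array at 15 Gy and 0 past the threshold adjusted over the list alone. The members with the lowest values, named after their values were seen, were the GABA synthesis gene gad1b (−2.55), the vesicular GABA transporter gene slc32a1 (5.26-fold lower) and the synaptic vesicle gene sypb (−2.20). Replicate 1 was again the lowest. In replicates 1, 2 and 3, gad1b stood at 6.36, 9.27 and 8.64 (control 10.64) and sypb at 7.49, 9.70 and 9.25 (control 11.01). The actin 5′ to 3′ ratio was also higher in every array at 15 Gy than in the control array. Downward from the control, the photoreceptor median (−1.52 at 12 Gy) ranked the 5 arrays in the same order as that ratio. Glia and myelin genes did not pass as a group (24 genes, median −0.55, camera adjusted p = 0.48), although their median lay below the central range of random lists of the same size and expression (−0.10 to 0.38), and 5 of them rose and 2 fell adjusted over the list alone. The intermediate filament gene vim (1.18) and apoeb (2.62) were among those that rose, and the 7 became 0, 1 and 0 without replicate 1, 2 or 3. Lens genes did not pass either (13 genes, median 0.05, mean 0.34, downward in the test, camera adjusted p = 0.88).

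Epidermal genes rose as a group (43 genes, median 1.11, camera adjusted p = 2.59e-07; adjusted p = 0.782 with an estimated correlation). Adjusted over the list alone, 18 rose and 2 fell. The largest increases were in anxa2a (4.03, 16.3-fold), the simple-epithelium keratin gene krt18a.1 (3.78, 13.7-fold), s100a10b (3.54) and anxa1a (2.77), and the keratin genes krt15 (−0.61) and krt1-19e (−0.46) fell. Without replicate 1, 2 or 3 the 20 members that passed became 0, 28 and 0. Heat shock and protein folding genes rose as a group (40 genes, median 0.66, camera adjusted p = 7.63e-07, adjusted p = 0.782 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Of the 40, 37 lay above the control in every array at 15 Gy, a position that 41.0% of all named genes shared. Fast skeletal muscle genes rose as a group (35 genes, median 0.72, camera adjusted p = 0.000439; adjusted p = 0.782 with an estimated correlation), again with 0 members past the threshold adjusted over the list alone.

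Among metabolic lists, glutathione and oxidative stress genes rose as a group (35 genes, median 0.54, camera adjusted p = 0.000395; adjusted p = 0.782 with an estimated correlation). The 4 members that rose adjusted over the list alone were the thioredoxin gene txnb (3.36), the glutathione peroxidase genes gpx1b (2.18) and gpx1a (0.67), and taldo1 (0.71). Glucose and fasting genes rose as a group (41 genes, median 0.36, camera adjusted p = 0.0248; adjusted p = 0.782 with an estimated correlation), and igfbp1a (2.91), sik1 (0.98) and g6pc1a.2 (0.72) rose adjusted over the list alone. The glucose median was 0.60, 0.07 and 0.39 in replicates 1, 2 and 3, and without replicate 3 it was 0.18 and the group call was lost (adjusted p = 0.158). Cholesterol synthesis genes fell as a group (19 genes, median −0.24, camera adjusted p = 0.000901; adjusted p = 0.782 with an estimated correlation), with hmgcs1 (−0.85) and fdft1 (−0.68) past the threshold adjusted over the list alone. Counts of members of these 3 lists that passed were 0, 13 and 0 for glutathione, 0, 2 and 0 for glucose, and 0, 0 and 0 for cholesterol without replicate 1, 2 or 3.

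Proteasome genes rose (47 genes, median 0.46, camera adjusted p = 0.000395) and circadian clock genes fell (31 genes, median −0.31, camera adjusted p = 0.00114) as groups, both with adjusted p = 0.782 with an estimated correlation and 0 members past the threshold adjusted over the list alone. Exocrine pancreas genes fell as a group (21 genes, median −0.34, camera adjusted p = 0.0272; adjusted p = 0.782 with an estimated correlation), but the list median was −1.08, −0.24 and 0.17 in replicates 1, 2 and 3, and the call was lost without replicate 1 (adjusted p = 0.136) or replicate 2 (adjusted p = 0.0569) and without the dimmest 30% of probe sets (adjusted p = 0.0509). Ribosomal protein genes rose as a group (72 genes, median 0.22, camera adjusted p = 1.39e-07; adjusted p = 0.782 with an estimated correlation), but the call was lost after another quantile normalization (adjusted p = 0.0861) and after cyclic loess (adjusted p = 0.206), where the median turned to −0.041. Their median also lay within the central range of random lists of the same size and expression (0.12 to 0.37), so they were not higher than comparable genes.

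The remaining 14 lists did not pass at 15 Gy, with adjusted p between 0.053 and 0.799. Mitochondrial respiration had a median of 0.23, or 0.43, −0.07 and 0.35 in replicates 1, 2 and 3. That list passed without replicate 2 (median 0.37, adjusted p = 6.41e-08) and after median centring (adjusted p = 0.0392). The xenobiotic metabolism list passed without the dimmest 30% of probe sets (median 0.93). The medians were 0.42 for heart muscle, 0.37 for xenobiotic metabolism, 0.30 for the glucocorticoid response, 0.21 for ionocytes and kidney, and −0.24 for swim bladder and thyroid axis. They were 0.01 for blood vessels, 0.15 for red blood cells, −0.02 for lymphoid cells, −0.06 for vitellogenin and yolk, 0.05 for cartilage and bone, −0.07 for enterocytes and −0.04 for hypoxia and glycolysis. Pigment cell genes had a median of 0.00. The means of the swim bladder (0.04), vitellogenin (0.24), hypoxia (0.25) and pigment (0.17) lists were positive, although the test pointed downward in each. Against random lists of the same size and expression, the medians of heart muscle and xenobiotic metabolism lay above the central range, and those of swim bladder and of cell cycle genes lay below it. Single members of these lists rose adjusted over the list alone, among them the detoxification gene cyp1a (1.63), the glucocorticoid-responsive kinase gene sgk1 (4.60-fold), the endothelial genes plvapb (1.67) and cldn5a (1.16), the ion transporter gene slc12a3 (1.61), the protease gene ctsla (2.09) and the globin gene hbae3 (0.88). In the lymphoid list ccl25b (0.65) rose and gata3 (−0.53) fell.

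**Figure D2:**
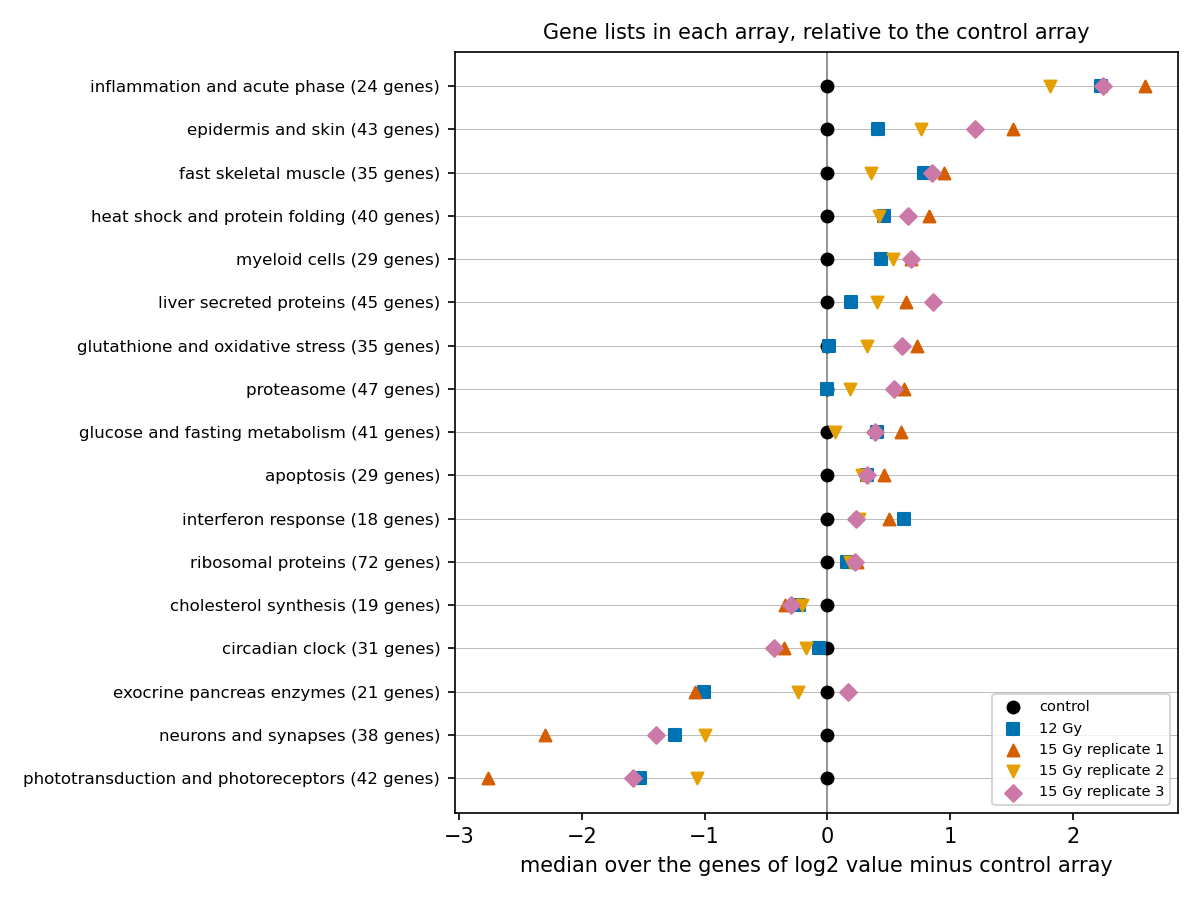
Each line of points is a reported gene list that passed the test at 15 Gy, with the median over its genes of the log2 value minus that of the control array (x axis) as a point per array, so that the control lies at 0. The inflammation list lay between 1.81 and 2.58 and the photoreceptor list between −2.77 and −1.06 in the 4 irradiated arrays.

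The next comparison asked what differed after the lower dose of 12 Gy. Inflammation genes were again higher and photoreceptor and neuron genes lower than in the control. With 1 probe set per named gene, that with the highest mean, the largest increases were those of mmp9 (73.8-fold), hsp70.3 (51.8-fold), mmp13a (43.0-fold), socs3a (35.8-fold) and timp2b (30.7-fold). The largest decreases, on the log2 scale, were those of opn1sw2 (−3.81), opn1mw1 (−3.60), opn1sw1 (−3.46), nme2a (−3.41) and rgs9a (−3.23). This comparison set 1 array against 1, with the spread taken from the 15 Gy arrays, so it had no replicate check of its own. With limma, 0 of 15502 probe sets passed (smallest adjusted p = 0.0562), and 2644 (17.1%) had an unadjusted p under 0.05, 1467 of them higher and 1177 lower. After another quantile normalization 4 passed.

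At 12 Gy, 14 of the 36 lists passed, 10 higher and 4 lower, and 0 with an estimated correlation. Inflammation genes rose as a group (median 2.23, camera adjusted p = 6.42e-11; adjusted p = 0.968 with an estimated correlation), and 19 of 24 rose adjusted over the list alone. Photoreceptor genes (median −1.52, camera adjusted p = 2.38e-06) and neuron genes (median −1.24, camera adjusted p = 1.89e-05) fell as groups, both with adjusted p = 0.968 with an estimated correlation, and all 42 and all 38 members lay below the control. Over all 15502 probe sets the median change at 12 Gy was −0.0090. Only rgs9b (−1.55) among the photoreceptor genes passed adjusted over the list alone, and 0 did without any single array at 15 Gy. The rgs9b value at 12 Gy (3.85) lay below the lower quartile of every array. The genes named whatever their value lay above the control by 1.96 (mdm2), 2.09 (ccng1), 0.89 (baxa) and 1.84 (gadd45aa) on the log2 scale. In the myeloid list 4 genes rose adjusted over the list alone, among them lcp1 (1.15) and ptprc (0.86), and the list rose as a group (median 0.44, camera adjusted p = 2.31e-05; adjusted p = 0.968 with an estimated correlation). Without replicate 1, 2 or 3 of 15 Gy, from which the spread was taken, the inflammation count became 20, 12 and 0 and the myeloid count 5, 0 and 0.

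Epidermal genes rose as a group at 12 Gy (median 0.41, camera adjusted p = 0.042; adjusted p = 0.97 with an estimated correlation), but the call was lost without 15 Gy replicate 1 (adjusted p = 0.107) or replicate 3 (adjusted p = 0.0859) and without the dimmest 30% of probe sets (adjusted p = 0.0573). Of these genes, 4 rose adjusted over the list alone, krt18a.1 (3.21), cldnb (2.37), cdh1 (2.21) and krt18b (1.72), and 3 fell, and the 7 became 0, 8 and 0 without replicate 1, 2 or 3. Fast skeletal muscle (0.78), heat shock (0.46), glucose and fasting (0.40), interferon (0.62), liver (0.19) and ribosomal protein (0.16) genes rose as groups, and exocrine pancreas genes (21 of 21 below the control) fell, all with adjusted p = 0.968 with an estimated correlation. Mitochondrial respiration genes fell (median −0.22, camera adjusted p = 0.0136; adjusted p = 0.97 with an estimated correlation), a call lost without 15 Gy replicate 1 (adjusted p = 0.0861). The ribosomal call was lost after another quantile normalization (adjusted p = 0.151) and cyclic loess (adjusted p = 0.440, median −0.035), and the median stood at percentile 65.3 among random lists of the same size and expression. Apoptosis (median 0.32) and cholesterol synthesis (−0.23) genes did not pass at 12 Gy. Both passed after another quantile normalization, after median centring and without the dimmest 30% of probe sets. Apoptosis genes also passed after cyclic loess and without 15 Gy replicate 1. Xenobiotic metabolism genes passed only without the dimmest 30% (median 0.87). The circadian clock list did not pass (median −0.07, mean 0.11, upward in the test, camera adjusted p = 0.812), but 7 of its 31 members passed adjusted over the list alone. The repressor genes cry2 (1.58), bhlhe41 (1.55), bhlhe40 (1.38) and ciarta (1.13), together with cry-dash (1.01) and tefa (0.82), rose, and the activator gene bmal1a (−1.14) fell; all but cry2 and bhlhe41 are named after their values were seen. This count was 0 without any single array at 15 Gy.

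The changes at both doses from the control resembled each other across probe sets. The Pearson correlation of the log2 changes at 12 Gy and 15 Gy across 15502 probe sets, which are not independent replicates, was 0.887. Because both changes were taken from the same control array, unchanged groups simulated with a shared control array already gave 0.613 (highest of 100 simulations, 0.650). The simulated probe sets varied independently, so these simulations leave out variation shared across probe sets. How far such variation would widen their range was not tested. The covariance was 0.397 against 0.0685 in the simulations, a difference of 0.329. The simulated control array was given the spread of the 15 Gy arrays. A control array off by more than that spread would raise both the correlation and the covariance. These simulations therefore cannot show likeness beyond that of a shared control array. Of the 642 probe sets at least 2-fold higher in every 15 Gy array, 538 (83.8%) were also at least 2-fold higher at 12 Gy, and of the 435 lower ones 403 (92.6%) were also lower. Independent lists of these sizes would share 34.8 and 20.7, a reckoning that leaves out the shared control array. The simulated unchanged groups shared 23.4 and 24.9. How many simulated probe sets were 2-fold in every 15 Gy array was not counted. These counts thus give no share to set beside 83.8% and 92.6%. With a lone control array, the controls could not be divided between the comparisons.

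The last comparison set 15 Gy against 12 Gy. By the same rule of 1 probe set per named gene, the largest increases at 15 Gy were those of the stress-response gene ddit4 (6.81-fold), anxa6 (3.88-fold), tcnbb (3.84-fold), s100w (3.80-fold) and icn2 (3.62-fold). The largest decreases were those of ptgdsb.2 (3.97-fold), the activity-dependent transcription factor gene npas4a (3.85-fold), txlnba (3.60-fold), pik3ip1 (3.44-fold) and the tyrosine aminotransferase gene tat (3.40-fold). Their adjusted p-values lay between 0.513 and 0.598. For ddit4 the 12 Gy array stood at 3.67, below its lower quartile (4.69) and below the control (5.04), so its fold rests on a single dim value. The 15 Gy means of txlnba (3.31) and tat (4.33) also lay below the lower quartile of every array. With limma, 1 of 15502 probe sets passed, a probe set for the coatomer gene copb2, which was lower at 15 Gy by −6.51 on the log2 scale (adjusted p = 0.0285). It stood at 8.84 at 12 Gy, 6.45 above the control, and at 2.34 ± 0.04 (SD, n = 3) at 15 Gy, whereas the other copb2 probe sets differed by 0.21 and 0.19. The control and 15 Gy values lay below the lower quartile of every array and near its lowest values, so the size of these differences rests on values near the floor. The call was lost without any single array at 15 Gy. At an unadjusted p of 0.05, 1383 probe sets (8.92%) passed.

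Of the 36 lists, 7 passed between the doses, 4 higher and 3 lower at 15 Gy, and 0 with an estimated correlation. After another quantile normalization 14 passed, 6 higher and 8 lower, and after cyclic loess 12 passed, 6 higher and 6 lower. Circadian clock genes were lower as a group at 15 Gy (median −0.22, camera adjusted p = 3.81e-08; adjusted p = 0.849 with an estimated correlation). Adjusted over the list alone, 5 fell, cry2 (−1.64), bhlhe41 (−1.54), ciarta (−1.01), cry-dash (−0.96) and tefa (−0.85), and bmal1a was 0.40 higher without passing. Without replicate 1, 2 or 3 this count became 0, 4 and 0. Epidermal genes rose (median 0.60, camera adjusted p = 4.20e-09, adjusted p = 0.849 with an estimated correlation), with the keratin genes krt5 (0.97) and krt1-19e (1.34) past the threshold adjusted over the list alone. That count became 0, 3 and 0 without replicate 1, 2 or 3. The smallest difference of both lists from 12 Gy was in replicate 2 (medians in replicates 1, 2 and 3: −0.43, −0.12 and −0.34 for the clock, 0.92, 0.27 and 0.69 for epidermis). The actin 5′ to 3′ ratio of replicate 2 (0.0350) was also the closest to that at 12 Gy (0.0354).

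Mitochondrial respiration genes (median 0.44, camera adjusted p = 3.92e-09), proteasome genes (median 0.38, camera adjusted p = 5.15e-06) and glutathione genes (median 0.34, camera adjusted p = 0.000127) rose as groups between 12 Gy and 15 Gy, each with adjusted p = 0.849 with an estimated correlation. In replicates 1, 2 and 3 the medians were 0.67, 0.15 and 0.57 for mitochondria, 0.56, 0.15 and 0.41 for the proteasome, and 0.51, 0.14 and 0.47 for glutathione, in the order of the actin ratios (0.129, 0.0350 and 0.108). Neuron genes fell as a group (median −0.34, camera adjusted p = 0.0192; adjusted p = 0.884 with an estimated correlation), but without replicate 1 the median was 0.03 and the call was lost (adjusted p = 0.898). Inflammation genes fell slightly as a group (median −0.08, camera adjusted p = 0.0413; adjusted p = 0.849 with an estimated correlation), a call lost after median centring (adjusted p = 0.0604) or without replicate 3 (adjusted p = 0.0513). Without replicate 2 it was lost as well, and the median turned to 0.0067 (adjusted p = 0.315). Photoreceptor genes (median −0.16, adjusted p = 0.0595) did not pass. The difference from 12 Gy was 0.35 for mdm2, 0.10 for ccng1, 0.14 for baxa and 0.64 for gadd45aa. The photoreceptor list passed without replicate 2 (adjusted p = 0.000635) or replicate 3 (adjusted p = 0.0244).

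**Figure D3:**
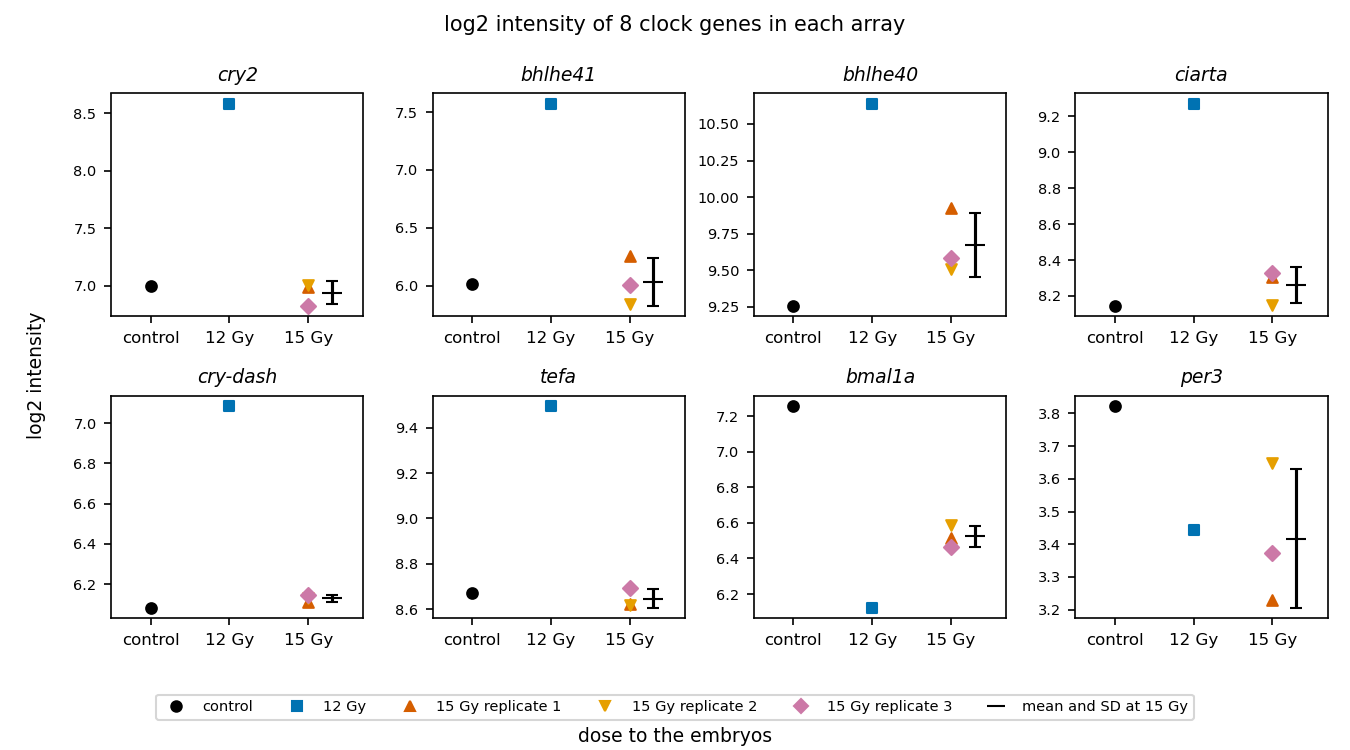
Each panel shows the log2 intensity of a circadian clock gene (y axis, own range) by dose (x axis), with a point per array and, at 15 Gy, the mean and SD of the 3 arrays. For cry2 the 12 Gy array stood at 8.58, whereas the control stood at 7.00 and the 15 Gy arrays between 6.83 and 7.00.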

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

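The tests of explanations in this part were chosen after the results were seen, whereas the comparison of the doses was planned. Between 12 Gy and 15 Gy, 7 lists and 1 probe set passed the test of the difference. The list medians (15 Gy minus 12 Gy) were 0.60 for epidermis, 0.44 for mitochondrial respiration, 0.38 for the proteasome, 0.34 for glutathione, −0.076 for inflammation, −0.22 for the circadian clock and −0.34 for neurons. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.849), and the median turned to 0.031 for neurons without replicate 1 and to 0.0067 for inflammation without replicate 2. In data that entered no comparison, the spiked poly-A control probe sets were higher at 12 Gy than in the control array by a median of 0.62 on the log2 scale (24 of 24 higher), and the hybridization controls by 0.45 (17 of 18 higher). In 15 Gy replicates 1, 2 and 3 the medians were 0.06, 0.17 and −0.32 for the poly-A controls and −0.31, −0.01 and −0.21 for the hybridization controls.

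The first pattern was the higher inflammation genes and lower photoreceptor and neuron genes in all irradiated arrays. Differences between pairs of 15 Gy arrays, which involve no control, correlated with 12 Gy minus control with r of at least 0.775 in size over the 104 members of the 3 lists, but also with 0.707, 0.632 and 0.481 over all probe sets. This argues against the control array as the only reason these genes vary together, but the relation runs through the whole array, and whether the control's own levels are off stays open. A lower share of nervous tissue as the only change would raise other tissues alike. Epidermal genes, however, exceeded enterocyte genes by at least 0.79 in every 15 Gy array (SD 0.48), and by 0.57 at 12 Gy, little more than that SD. All these gaps were taken from the same control array. That SD is the spread of the 15 Gy arrays alone and leaves out any error of the control. RNA integrity cannot be told apart from dose, since GAPDH's 5′ to 3′ ratio was 1.02 times that of the control at 12 Gy while actin's was 2.07 times, and an effect of the protons remains open and untested with a lone control array.

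The clock genes of the 12 Gy array were the next pattern: cry2, bhlhe41, ciarta, cry-dash and tefa lay above both the control and the 15 Gy arrays. A candidate explanation is collection of the 12 Gy larvae at another time of day. The activator bmal1a moved against the repressors (0.40 higher at 15 Gy than at 12 Gy), but the activators clocka (−0.37) and clockb (−0.20) moved with them, and bmal1a at 15 Gy stayed at −0.73 from the control. With 1 array at 12 Gy, this cannot be told apart from an effect of the dose or of the pool, and no collection time was given in the sources used here.

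The last pattern was a copb2 probe set that was −6.51 lower at 15 Gy than at 12 Gy. A change across the whole copb2 transcript is argued against by its other probe sets, which differed by 0.19 and 0.21 in the other direction. The names of these probe sets share a stem that the called one lacks, so they may not be separate checks. They cannot exclude a change limited to the stretch that the called probe set reads. The size of the difference rests on control and 15 Gy values near the lowest on the arrays. No other explanation of this signal was tested.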

How the results depend on the processing

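No paired analysis was possible because the groups share only replicate number 1. The tests without tied probe sets, on the brightest probe sets and of the 2-fold counts, and fry, were chosen after seeing the data; all other alternatives were planned. For 15 Gy against control, 0 probe sets passed under all alternatives except all 4 irradiated arrays as 1 group (6) and the brightest probe sets without ties (49, all higher, of 3405 tested). That filter uses the mean over mostly irradiated arrays, which favours genes higher in them. For 12 Gy against control, 4 passed after quantile normalization, 1 after median centring, 2 after cyclic loess, 1 with a trended prior, 2 without tied probe sets and 0 otherwise. For 15 Gy against 12 Gy, the call of 1 became 0 without the dimmest 30%, with 1 probe set per gene, on the brightest probe sets, and in the range 0 to 0 without each 15 Gy array, where 1 residual degree of freedom was left.

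The correlation of the changes at both doses was 0.899 without the dimmest 30% and between 0.874 and 0.894 without each 15 Gy array, against 0.887. The total of 1077 probe sets at least 2-fold from the control in every 15 Gy array became 1077 to 1887 without each array and 1027 to 1110 under the filter and normalizations. Lists that passed fell from 18, 14 and 7 to 0, 0 and 0 with an estimated correlation, and likewise to 0, 0 and 0 with fry in place of camera. The estimated correlation also passed 0 of 4 moved lists in simulated data, so it cannot decide these calls. Between the doses, 7 lists became 14 after quantile normalization, 12 after cyclic loess, 18 by random lists and 8 to 13 without each 15 Gy array. Against the control, 17 to 22 lists passed at 15 Gy and 13 to 17 at 12 Gy under every alternative but these. Among lists that passed, 4 of 351 medians under alternatives had the other sign: those of ribosomal proteins after cyclic loess (−0.041 at 15 Gy, −0.035 at 12 Gy), of neurons between the doses without replicate 1 (0.031, the end of a range that began at −0.601 without replicate 2), and of inflammation between the doses without replicate 2 (0.0067, the end of a range that began at −0.237 without replicate 1). Among lists that had not passed, 65 of 621 had the other sign, such as glucose and fasting between the doses after quantile normalization, which then passed (0.0046). The largest of these 65 medians was 0.503 in size. Except where noted, the cause was not tested.

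For 127 log2 changes of named genes, 1007 values were obtained under alternatives. These were the normalizations, the dim filter, the mean of a gene's probe sets and each 15 Gy array left out. Of these values, 0 changed sign and 0 passed over all probe sets. For genes chosen with all 15 Gy arrays on the same side, leaving out a 15 Gy array could not change the sign. Changes of the lower dose from the control do not use the 15 Gy arrays, so their size could not move either. The signs without each 15 Gy array are therefore no test of these changes. With the irradiated arrays as 1 group mmp9, cdh1 and rgs9b passed (adjusted p = 0.0395), and on the brightest probe sets mmp9, socs3a, timp2b, cebpb and ccng1 were among those that passed. Without replicate 3, no list member passed adjusted over its list alone in any list; the prior degrees of freedom were then 0.777 and 1122 probe sets had an unadjusted p under 0.05, against 3790 and 4479 without replicate 1 or 2. The prior degrees of freedom were 0.752 without replicate 1 and 1.02 without replicate 2, so the prior alone does not account for the lower count without replicate 3. Signal over background could not be assessed without scanner values.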

Other observations

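Gene families chosen by symbol after the values were seen, and not tested, are given here as values. Of 6 measured genes of the fos and jun family, whose proteins form the AP-1 transcription factor, 5 were at least 2-fold higher than the control in every 15 Gy array and 5 at 12 Gy. They were junba (3.37 at 15 Gy, 3.61 at 12 Gy), junbb (2.75, 2.69), fosl2 (2.56, 2.16), fosab (2.47, 3.26) and jun (2.28, 2.56). Of 7 matrix metallopeptidase genes, 5 were higher by this measure, among them mmp2 (3.51), mmp14b (1.71) and mmp14a (1.32), and of 13 cathepsin genes 4 were, led by ctsk (2.73). Of 16 complement genes, 6 were higher, led by c4b (3.49) and c6.2 (2.71). Over all 8793 named genes, 5.09% were at least 2-fold higher in every 15 Gy array and 2.49% at least 2-fold lower.

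Of 6 synaptotagmin genes, 3 were at least 2-fold lower in every 15 Gy array, syt5a (−2.41), syt1a (−2.19) and syt9a (−1.94). Of 14 tubulin genes, tuba2 (−1.91) and tubb4bl (−2.22) were lower and tuba5 (1.51) was higher. Of 42 hox genes and 7 gamma crystallin genes, 0 were 2-fold higher or lower in every 15 Gy array. Of 10 S100-type genes, 5 were at least 2-fold higher in every 15 Gy array, s100a10b (3.54), s100u (2.19), s100w, icn and s100v1 (1.55). Of these, s100w stood at 1.75 from the control at 15 Gy and −0.18 at 12 Gy, and icn at 1.62 and 0.12, but neither passed between the doses (adjusted p = 0.520 for both).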
